A study of Arabidopsis thaliana with 6 samples.

How the data were processed

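Whole seedlings of the Ler accession were sampled at 7 days after germination, with 3 libraries of wild type and 3 of the dme mutant, grouped by their titles. Per the labels' protocols, seedlings grew on MS plates, RNA was extracted with an RNeasy plant kit and libraries were made at BGI. The submitters' processing notes name Trimmomatic 0.36, HISAT2 2.1.0, StringTie 2.1.3 and the genome build TAIR10. The tool of the differential test, the counting of reads and the use of strand are not given in the sources used here, so reads of overlapping, antisense and near-identical genes cannot be told apart.

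One table was analysed, which holds the authors' own comparison of the genotypes. Its mean normalized count over all libraries is a signal that the authors deposited per gene, per the file headers, with a scaling that is not stated. Its change is given by the authors as a log2 fold change and as a linear fold, the latter equal to 2 raised to the former in every row. Its adjusted p-value was deposited by the authors, with a method of adjustment that is not stated. The smallest absolute log2 fold change among the 5322 rows was 1.00 and the largest adjusted p was 0.0498, so the table holds only genes past both thresholds. The number of columns of per-sample values was 0. The fits planned before the data were examined need values per library and were not run. The authors' values are reported instead, with no error of their own, and the tests of the main results were made on counts of listed genes. Tests on the size of folds and on bounds of their standard errors were added after seeing the data. The depth of each library is unknown.

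In 22 rows, 11 pairs share a gene name and all values under 2 locus codes, as when values are joined by name. Each pair was counted once and its locus is ambiguous. The difference between the log2 mean and the absolute log2 fold change took a fixed value in 290 genes, at -3.40 in the 235 higher and between -3.49 and -3.47 in the 55 lower ones, while the next genes lay at -2.43 and -2.50. A fold that depends on the mean alone arises when 1 genotype has no reads. In 13 higher genes the WT mean implied by the fold, times 3 libraries, lay between 1.10 and 1.12, and in 29 between 2.03 and 2.07, near whole reads, so the folds appear to be unshrunken ratios of 3 against 3 libraries. No fold is reported for the 290 genes.

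Genes were named by a rule fixed before the data were examined: DME, ROS1, DML2 and DML3, the 12 largest rises and the 12 largest falls, and up to 4 members of each of 21 gene lists with the smallest adjusted p. The rule asks for replicates that do not overlap, which could not be checked, and for 5 CPM, replaced by an implied mean of at least 32.8 in the higher genotype, which is 5 CPM of the summed means of the listed genes. Members were matched by locus code. Of the locus codes, 5292 of 5322 matched the annotation of assembly TAIR10.1, which was used only for names, gene order and distances, and no coordinates are given because the authors' build is TAIR10. Genes named outside the rule were chosen after their values were seen.

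The direction of the listed members of a list was compared with all other listed genes by two-sided Fisher's exact tests, adjusted by the Benjamini-Hochberg method over the 21 lists. A count adjusted over the list alone could not be computed, since unadjusted p-values of all members are not used here. Transposable element genes were taken from the gene types in the table. A bound on the standard error of a fold was computed as the absolute log2 fold change over the normal quantile of its adjusted p, which assumes a Wald test and an adjusted p no smaller than the p. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. The steps were tested on simulated data, with 100 lists of 20 listed genes per setting set against the 5311 measurements. At an unadjusted p under 0.05, 3 were called with the share of higher genes of the whole table. With a share of 95%, 77 were called, and with a share of 30%, 99. Members were drawn independently, so these rates do not carry over to genes that change together. Nor do they carry over to lists with fewer listed members, as most lists had, or to calls adjusted over the 21 lists. In 2783 simulated genes past the thresholds the bound was below the true standard error in 0. This holds by construction, since the simulated p-values came from a Wald test. Whether the authors' test meets that assumption was not tested. Alternatives tried were an adjusted p under 0.01, windows of 1 and 4 Mb and leaving out genes near DME, and, chosen after seeing the data, a 4-fold threshold, a mean of at least 50, repeated rows counted, genes without reads in 1 genotype left out, and shifts of all log2 fold changes by 0.5 or 1.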

Results

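The transcriptomes of whole Arabidopsis thaliana seedlings of the Ler accession were compared at 7 days after germination between wild type (WT, 3 libraries) and a dme mutant (3 libraries). DME encodes a DNA glycosylase that removes 5-methylcytosine from DNA, and the comparison asks which seedling transcripts differ when DME is mutated. The values analysed here are those of the authors' deposited table, which lists for each gene a mean normalized count over all libraries, a log2 fold change and an adjusted p, and holds only genes with at least a 2-fold change and an adjusted p under 0.05. It gives no value per library, no standard error and no sequencing depth, so neither the spread between replicates nor the depth behind a value can be stated, and the adjusted p is the authors' own measure of change against that spread. No label says that the 3 libraries of a genotype came from separate cultures, so the p-values measure the spread between these samples, which may be technical. A gene outside the table may have changed by less, missed the threshold or not been tested. Fold changes were read as dme over WT from the name of the table, since its header does not name the numerator.

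DME (AT5G04560, chromosome 5), the mutated gene, was lower in dme in the authors' deposited table, with a log2 fold change of -1.55, a mean normalized count of 2178 and an adjusted p of 4.88e-17. A transcript of DME was thus still counted, and the table does not say which part of the gene the reads came from. The 3 other members of the glycosylase family, ROS1, DML2 and DML3, were not among the listed genes.

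More genes were higher than lower in dme. After 11 pairs of rows with identical values were each counted once, the authors' deposited table held 5311 measurements, of which 3867 (72.8%) were higher and 1444 (27.2%) lower. Among genes with reads in both genotypes, the median log2 fold change in the authors' deposited table was 1.98 for the higher and -1.38 for the lower genes. At a 4-fold threshold 2035 genes were higher and 343 lower, a share of 85.6% higher. That share depends on how the libraries were scaled to each other, which cannot be checked without values per library: it was 70.0% with all log2 fold changes of the authors' deposited table shifted by -0.5 and 42.0% with a shift of -1. With -1 all 1444 lower genes pass the 4-fold threshold by construction. The shifts are arithmetic examples, and no value here shows that such a shift applies.

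**Figure D1:**
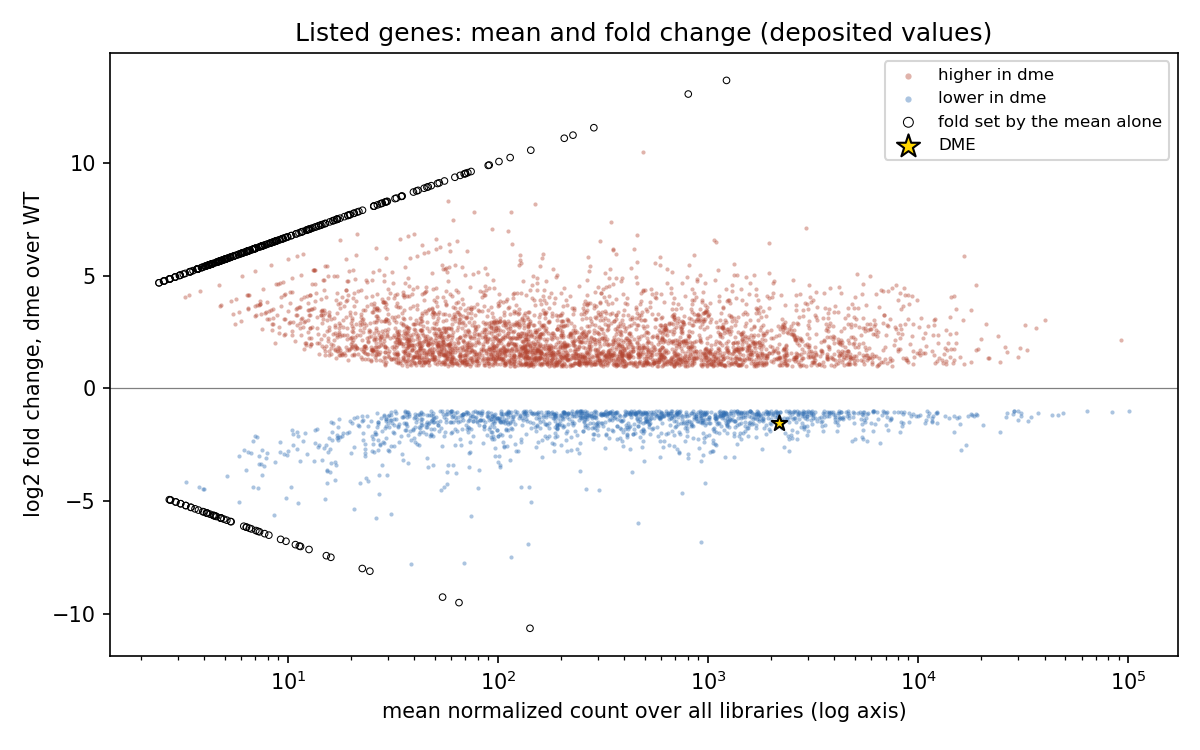
Log2 fold change (dme over WT) against the mean normalized count over all libraries (log axis) for the 5311 measurements of the authors' deposited table, with DME marked by a star. Open circles are the 290 genes whose fold change depends on the mean alone, 235 higher and 55 lower, and the empty band around 0 is the 2-fold threshold of the table.

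For 290 of the genes the fold change in the authors' deposited table was a fixed function of the mean, as when 1 genotype has no reads. Of these, 235 were higher in dme and 55 lower. Their fitted folds carry no size of change, so only their means are given. By the rule for named genes, 11 of the 12 largest rises were of this kind. They include CYP82C4, a cytochrome P450 of coumarin synthesis under iron deficiency, with a mean normalized count of 805 in the authors' deposited table. AT1G35115 and SADHU2-1, both typed as transposable element genes, had mean normalized counts of 1225 and 286 in the authors' deposited table. Those of BGLU24, AT5G57010, AT3G61400, KIN1, PEP7 and PP2-B6 lay between 89.9 and 227.6 in the authors' deposited table. Of the other 2, AT1G25682 had an adjusted p of 0.0145 and CYP89A9 of 0.0275 in the authors' deposited table, weak for means of 143.3 and 74.5. The remaining gene of the 12, AT2G39110, a protein kinase gene, was higher by a log2 fold change of 10.47 in the authors' deposited table, from an implied WT mean of 0.688 normalized counts.

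Among the 12 largest falls, 5 were of the same kind in the authors' deposited table: AT2G45910, CRK18, AT2G26750, PDF1.2b and AT1G35280. PR1, a marker of salicylic acid responses, had a log2 fold change of -6.92 in the authors' deposited table, with an adjusted p of 9.96e-28. KEA3, a potassium efflux antiporter of the thylakoid, had a log2 fold change of -6.82 at a mean normalized count of 927.7 in the authors' deposited table. AT3G07690 stood at -7.49, AIG1 at -5.97 and GPX7 at -5.74 on the log2 scale of the authors' deposited table. PDF1.2, a plant defensin gene, stood at -7.73 in the authors' deposited table. SFR6 stood at -7.77, but with an adjusted p of 0.0170 in the authors' deposited table. Ranked by the same rule among genes with reads in both genotypes, a choice made after the values were seen, the rises were led after AT2G39110 by AT1G35320 (8.29 on the log2 scale of the authors' deposited table) and by NAS2, a nicotianamine synthase gene (8.18). The implied WT means of these 2 were 0.369 and 1.03 normalized counts, and the implied dme means of SFR6, PDF1.2, GPX7, AT3G07690 and PR1 lay between 0.352 and 2.27, so the sizes and ranks of these folds and of that of AT2G39110 rest on few reads.

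Of the 21 gene lists fixed before the data were examined, which hold 544 genes, 189 members were listed. The direction of each list's listed members was compared with that of all other listed genes by a two-sided Fisher's exact test, adjusted over the 21 lists by the Benjamini-Hochberg method. The test was chosen after the table and the counts per list had been seen, in place of a set test that needs values per library. Genes are not independent, so its p-values describe this table. A list that goes higher can hardly pass with few listed members: 12 of 12 higher gives an exact p of 0.0447 before adjustment. One list passed, that of photosynthesis and chlorophyll. The test compares direction only, and the share of each list that was listed was not tested. For photosynthesis and chlorophyll it was 7 of 48, below the 34.7% of all 544 list members. It was also below the 18.6% of all annotated protein-coding genes, which include genes that may not have been tested. Larger shares were listed of root markers (16 of 20), heat shock (11 of 14) and iron deficiency genes (12 of 17). The same held for jasmonate (17 of 23) and salicylic acid genes (21 of 30). Some lists had smaller shares, such as the imprinted genes (2 of 24).

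All 7 listed genes of photosynthesis and chlorophyll were lower in dme, of 48 on the list (adjusted exact p = 0.00228, Fisher's exact test), and the other 41 were not listed. They were the transcription factors GLK1 and GLK2, which drive chloroplast development, the chlorophyll synthesis genes CAO and GUN4, and the light-harvesting genes LHCB1.1, LHCB2.1 and LHCB2.2. GLK2 had a log2 fold change of -2.15, CAO of -1.55 and GUN4 of -1.27 in the authors' deposited table. LHCB2.1 stood at -1.20 there, and reads of LHCB genes may be shared between near-identical copies. At a 4-fold threshold only GLK2 was left and the list was no longer called (adjusted exact p = 0.519).

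Root markers went the other way without passing the test of direction (15 higher and 1 lower of 20, adjusted exact p = 0.202). SULTR1;2, a sulfate transporter of the root, and THAS1, the thalianol synthase, both rose by a log2 fold change of 4.60 in the authors' deposited table, and the peroxidase gene PER3 rose 8.60-fold. BGLU23, the abundant beta-glucosidase of root ER bodies, rose by 2.14 at a mean normalized count of 92389 in the authors' deposited table. CASP1 to CASP4, which build the Casparian strip of the endodermis, were all higher, with log2 fold changes from 1.77 (CASP4) to 6.19 (CASP2, from an implied WT mean of 1.37 normalized counts) in the authors' deposited table. TIP2;3, an aquaporin gene, was the 1 lower member, at -1.01 in the authors' deposited table. Of the list of iron deficiency, 12 of 17 members were higher and 0 lower (adjusted exact p = 0.117). FRO2, the root ferric reductase, rose by a log2 fold change of 5.27, the scopoletin synthesis gene F6'H1 by 4.68, the regulator FIT by 2.51 and BHLH100 by 5.17 in the authors' deposited table. Root hair and trichome genes were 9 higher and 1 lower of 26 (adjusted exact p = 0.581). Those with the smallest adjusted p, not the largest folds, were RBOHC at 3.83, RHD6 at 2.94 and RSL2 at 2.23 on the log2 scale of the authors' deposited table, and WER, 8.02-fold higher.

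Defence genes were listed in both directions. Of 30 genes of salicylic acid and immunity, 16 were higher and 5 lower (adjusted exact p = 1.0). SARD1, PAD4, EDS1 and EDS5, which act in salicylic acid synthesis and signalling, rose by log2 fold changes of 2.83, 2.16, 1.85 and 3.39 in the authors' deposited table. The pathogenesis-related genes PR1, PR2 and PR5 fell instead, with PR2 at -2.70 and PR5 at -1.62 in the authors' deposited table. Of 23 genes of jasmonate and ethylene defence, 12 were higher and 5 lower (adjusted exact p = 1.0). The chitinase gene PR3 was higher with an adjusted p of 2.07e-284, and the jasmonate synthesis gene OPR3 by 4.31, and the repressor genes JAZ2 and JAZ10 by 2.56 and 3.31 on the log2 scale of the authors' deposited table. The 5 lower members were LOX2, PDF1.3 and PDF1.2a, b and c, whose near-identical sequences may share reads. Of 14 heat shock genes, 11 were higher and 0 lower (adjusted exact p = 0.117). HSP90.1 was higher with an adjusted p of 2.17e-95, and HSP101 rose by 2.06, HSP17.4 by 2.98 and HSP17.8 by 2.15 on the log2 scale of the authors' deposited table. Of 25 genes of abscisic acid, cold and drought, 8 were higher and 2 lower (adjusted exact p = 1.0). The dehydrin gene LTI30 rose by 4.42 and ERD14 by 1.26, whereas RAB18 had a log2 fold change of -2.09 in the authors' deposited table. KIN1 has a near-identical neighbour, KIN2, so that reads may be shared between them.

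**Figure D2:**
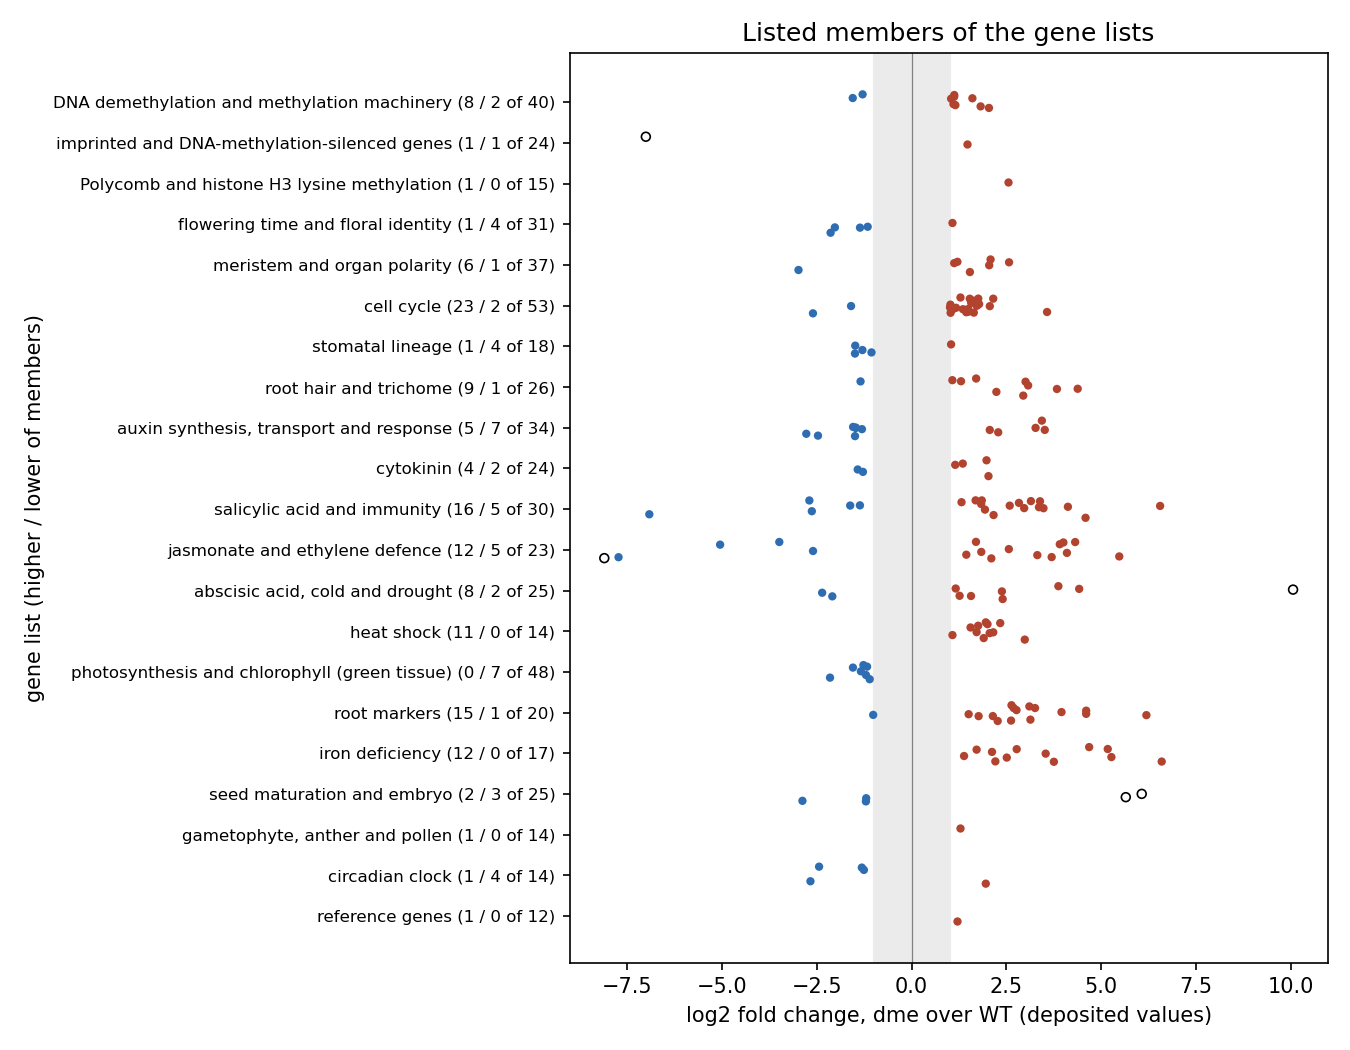
Log2 fold change (dme over WT) of each listed member of the 21 gene lists in the authors' deposited table, with the number higher, lower and on the list beside each name. Red points are higher and blue points lower in dme, open circles are genes whose fold depends on the mean alone, and the grey band holds the changes under 2-fold that the table leaves out. All 7 listed photosynthesis genes lie on the lower side and all 12 listed iron deficiency genes on the higher side.

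Of 53 cell cycle genes, 23 were higher and 2 lower (adjusted exact p = 0.117). The mitotic cyclin gene CYCB1;3 rose by a log2 fold change of 2.15, the cytokinesis kinesin gene HINKEL by 2.06 and the ribonucleotide reductase gene TSO2 by 1.29 in the authors' deposited table. KRP4, an inhibitor of cyclin-dependent kinases, had a log2 fold change of -1.60 in the authors' deposited table. Of 37 genes of meristem and organ polarity, 6 were higher and 1 lower (adjusted exact p = 1.0). The root stem cell regulators PLT1, PLT2 and BBM rose by 2.57, 2.04 and 1.54 on the log2 scale of the authors' deposited table, while BRC1, which represses bud outgrowth, stood at -2.98. Of 34 auxin genes, 5 were higher and 7 lower (adjusted exact p = 0.0949). The efflux carrier gene PIN2 rose by 3.51, while PIN3, PIN4 and GH3.5 stood at -1.48, -1.49 and -1.54 on the log2 scale of the authors' deposited table. Of 24 cytokinin genes, 4 were higher and 2 lower (adjusted exact p = 1.0), with ARR5 at 1.35, CKX4 at 1.97, ARR9 at -1.29 and CKX1 at -1.42 in the authors' deposited table.

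Of 18 genes of the stomatal lineage, 1 was higher and 4 lower (adjusted exact p = 0.0949). FAMA and TMM, which act in guard cell formation and stomatal patterning, stood at -1.30 and -1.49 on the log2 scale of the authors' deposited table. BASL was at -1.49 and HDG2 at -1.06 in the authors' deposited table. Of 14 circadian clock genes, 1 was higher and 4 lower (adjusted exact p = 0.0949), with RVE1 at -2.44, LHY at -1.31, PRR9 at -2.67 and CCA1 at -1.26 in the authors' deposited table. The hour of harvest is not given in the sources used here. Of 31 genes of flowering time and floral identity, 1 was higher and 4 lower (adjusted exact p = 0.0949). The floral repressor FLC stood at -2.02, SEP4 at -1.36 and AP1 at -1.16, while MAF2, a relative of FLC, stood at 1.08 on the log2 scale of the authors' deposited table.

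Of 40 genes of DNA demethylation and methylation, 8 were higher and 2 lower (adjusted exact p = 1.0). DME itself, the mutated gene, was 1 of the 2 lower members. The methyltransferase gene CMT3 rose by a log2 fold change of 2.04 and VIM1 by 1.82 in the authors' deposited table, and AGO4 was 2.15-fold higher. Only 2 of 24 imprinted or methylation-silenced genes were listed, FH5 at 1.45 in the authors' deposited table and VIM5, which was lower and of the kind without reads in 1 genotype (adjusted exact p = 0.822). JMJ13, a histone demethylase gene, was the 1 listed member of 15 Polycomb and histone methylation genes, at 2.53 in the authors' deposited table (adjusted p of the list 1.0). Of 25 seed maturation genes, 2 were higher and 3 lower (adjusted exact p = 0.268). PAP85 stood at -2.88 and DOG1 at -1.20 in the authors' deposited table, and the higher SESA1 and SESA2 had mean normalized counts of 4.76 and 6.36. Among 14 gametophyte, anther and pollen genes AGL80 was higher, at 1.27 (adjusted p of the gene 0.0469 in the authors' deposited table, of the list 1.0). Among 12 reference genes GAPC1 was higher, at 1.19 in the authors' deposited table (adjusted p of the list 1.0).

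Transposable element genes were listed in both directions about equally, 38 higher and 39 lower of 77. Their share of higher genes was 49.4% (exact 95% interval 37.8 to 61.0%) against 73.2% of the other listed genes (p = 1.28e-05, two-sided Fisher's exact test). Of them, 14 had no reads in WT and 9 none in dme by the pattern of their folds. Among genes with a mean normalized count of at least 50, 9 of 18 were higher against 71.7% of the others, and with these fewer genes the difference was not called (p = 0.0622, Fisher's exact test). The genes tested but not listed are not known, so the share called could not be tested.

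The share of genes listed near DME did not pass its test. Of 979 annotated protein-coding genes within 2 Mb of DME, DME left out, 199 (20.3%) were listed, against 4893 of 26464 (18.5%) elsewhere (p = 0.155, two-sided Fisher's exact test). The 164 higher genes made up 16.8% near DME against 13.6% elsewhere (p = 0.00601, Fisher's exact test, not adjusted), and the 35 lower genes 3.58% against 4.89% (p = 0.0582). With 1 Mb the higher genes made up 16.2% against 13.7% (p = 0.0799) and with 4 Mb 15.5% against 13.6% (p = 0.0396, Fisher's exact tests, not adjusted). Over 112 windows of 1 Mb with 50 or more genes the share listed ranged from 2.48% to 25.4%, and no window passed the test of a higher share, adjusted over all windows including those with fewer than 50 genes (smallest adjusted p = 0.312, one-sided binomial test). The background is all annotated protein-coding genes, including genes that may not have been tested.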

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

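The thresholds of 4-fold and of a mean of at least 50, the counting of repeated rows, the removal of genes without reads in 1 genotype and the shifts were chosen after seeing the data. The counts of higher and lower genes stayed within 1.5 times under an adjusted p under 0.01, without genes within 2 Mb of DME, with a mean of at least 50, with repeated rows and without genes lacking reads in 1 genotype. At 4-fold they came to 2035 higher and 343 lower genes, fewer by construction. The share of higher genes at 4-fold was 85.6%, and 70.0%, 42.0% and 93.1% with log2 fold changes shifted by -0.5, -1 and 0.5. The moves follow from the arithmetic of a uniform shift, and the size of any real scaling error is unknown. Of 79 alternatives of list tests, 78 left the call as it was, and the photosynthesis list was no longer called at 4-fold (adjusted exact p = 0.519), where 1 gene was left. The direction relative to all listed genes reversed in 9 of the 79, all in lists that were not called. At 4-fold, where 85.6% of all genes were higher, the lists of meristem and polarity, cell cycle and salicylic acid went from above to below that share (adjusted exact p = 0.642 each), as did abscisic acid (adjusted exact p = 0.601), and cytokinin went from below to above it (adjusted exact p = 1.0). The imprinted and the jasmonate lists went from below to above the share with a mean of at least 50 and without genes lacking reads in 1 genotype (adjusted exact p = 1.0 each). Transposable element genes were higher in 49.2% against 73.9% of other genes with an adjusted p of each gene under 0.01 (Fisher's exact p = 7.15e-05). At a mean of at least 50 9 of 18 were higher against 71.7% of other genes, and the call was lost with fewer genes (exact p = 0.0622). The share listed near DME kept its direction and stayed uncalled with 1 Mb, 4 Mb and an adjusted p under 0.01. The share of higher genes near DME passed 0.05 before adjustment with 2 Mb (p = 0.00601) and 4 Mb (p = 0.0396) but not with 1 Mb (p = 0.0799, Fisher's exact tests). No paired analysis was possible because the table holds no values per library. For the same reason other tools, scalings, pseudocounts, low-value filters on libraries, each library left out in turn, camera and fry tests, other splits of the samples and the comparison of refitted with deposited calls were not run. Depth is unknown, so no limit of detection can be given, and genes outside the table cannot be called unchanged.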

Other observations

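All tests in this part were chosen after the table was seen, and its families and added lists were picked from it, so their counts are not independent evidence of direction. Families were taken from the descriptions in the authors' deposited table. Of 34 listed WRKY transcription factor genes 33 were higher in dme, of 38 peroxidase superfamily genes 38, of 26 glutathione S-transferase genes 25 and of 36 TIR-class immune receptor genes 33 (adjusted p of 0.000897, 3.6e-05, 0.00749 and 0.0137, Fisher's exact test over 12 families). NAC genes (33 of 37 higher, adjusted exact p = 0.0343) and kinesins (13 of 13, adjusted exact p = 0.0343) went the same way. Jacalin-related and mannose-binding lectins (20 of 22 higher, adjusted exact p = 0.0684), expansins (13 of 15, adjusted exact p = 0.417) and cytochromes P450 (54 of 75, adjusted exact p = 0.896) did not pass this test. GSTU24 rose by a log2 fold change of 5.04 and WRKY51 by 4.17 in the authors' deposited table. Other families went down. Of 33 SAUR-like auxin-responsive genes 27 were lower (adjusted exact p = 4.95e-10), with SAUR16 at -3.05 in the authors' deposited table. Of 54 pentatricopeptide and tetratricopeptide-like genes 42 were lower (adjusted exact p = 1.26e-13), and of 10 B-box genes 9 (adjusted exact p = 0.000181), with BBX15 at -2.24 in the authors' deposited table.

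Of 5 added lists, rapid touch and wound response had 23 of 36 members higher and 0 lower (adjusted exact p = 0.00684, Fisher's exact test). Sulfur deficiency genes were 8 higher and 0 lower of 15 (adjusted exact p = 0.196), with APR3 at 3.40 and LSU1 at 6.61, the latter from an implied WT mean of 0.688 normalized counts, in the authors' deposited table. DNA damage response genes were 7 higher and 0 lower of 24 (adjusted exact p = 0.251). BRCA1 and BARD1, partners in DNA repair, were both of the kind without reads in WT, with mean normalized counts of 62.4 and 28.1 in the authors' deposited table. Phosphate starvation had 2 higher of 10 (adjusted exact p = 1.0) and photorespiration 2 lower of 14 (adjusted exact p = 0.185), CAT2 at -1.02 and GLDP1 at -1.06 in the authors' deposited table. The mitochondrial rRNA genes RRN18 and RRN26 were higher, at 2.26 and 2.62, while 13 of 14 other listed organelle genes were lower, COX2 at -1.29 and ATP9 at -1.34 in the authors' deposited table.

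By the pattern of their folds, 290 genes had reads in 1 genotype only. A segment linked to DME that holds most of them would place most near it. However, 9 of the 250 protein-coding ones (3.60%, exact 95% interval 1.66 to 6.72%) lay within 2 Mb. They made up 0.919% of the 979 protein-coding genes there, against 0.911% elsewhere (p = 0.865, Fisher's exact test). A linked segment that holds few of these genes stays open. A few segments of another accession would crowd them, but the 12 fullest windows of 1 Mb held 62 (24.8%, exact 95% interval 19.6 to 30.6%). The median was 65 in 1000 draws of other listed genes, not matched on mean. However, 48 had another such gene among the 5 on either side, against a median of 23 and at most 44 in the draws. The windows speak only against a few segments that hold most of these genes, and many or small segments stay open. Counting noise was asked about for the 99 genes with an implied mean of at least 20 in the other genotype. Of them, 63 (63.6%, exact 95% interval 53.4 to 73.1%) had an adjusted p below 1e-06 in the authors' deposited table. These genes were picked by a high mean against no reads, from genes that all have an adjusted p under 0.05. Small p-values largely follow from that choice, so this share cannot decide on counting noise. The implied means of the 99 genes argue against counting noise alone. Each was at least 20 normalized counts in 1 genotype, against no reads in the other. On this scale 1 read summed over the 3 WT libraries appeared to come to about 1 normalized count. This holds as far as the pattern of the folds marks genes without reads. An implied mean averages 3 libraries that were not seen singly, so 1 library may supply most of its reads. Whether these genes differ in all libraries of a genotype therefore stays open. Adjacent copies sharing reads, small variants against the reference and genes switched on or off in dme stay open as untested, and 5 of the 99, AT2G45910, AT1G25682, CYP89A9, LUP2 and FU, had adjusted p values above 0.01 in the authors' deposited table.

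Of 20 root markers 15 were higher and 1 lower (adjusted exact p = 0.202), and of 17 iron deficiency genes 12 were higher and 0 lower (adjusted exact p = 0.117), so that neither list passed the test of direction. A larger share of root of unchanged makeup would raise markers expressed in root only by 1 factor, but their log2 fold changes ran from -1.01 to 6.19 in the authors' deposited table and differed beyond the largest standard errors their adjusted p values allow (Cochran Q = 490.5 over 16 genes, and 367.7 over the 15 higher ones). This argues against that share alone only if all of these markers are expressed in root only. Their expression in shoot was not measured here, and unequal expression there would also give unequal folds, so a larger share of root stays open. Whether the iron genes changed beyond the root markers cannot be told apart: their median was higher by 0.425 on the log2 scale (3.15 against 2.73, p = 0.497, permutation test over 12 and 16 genes), which does not settle it.

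The rapid touch and wound response genes may differ between libraries of 1 genotype. Their largest allowed standard errors had a median percentile of 96.0 among the 100 higher genes nearest in mean and fold, against 51.0 in random lists (permutation p = 0.0001, the smallest that 10000 random lists can give), and of 98.0 without the 4 genes that are also in the fixed lists. The median was 38.0 for root markers, 47.0 for root hair, 53.0 for cell cycle, 55.0 for iron deficiency, 65.5 for jasmonate, 68.0 for heat shock, 70.5 for DNA methylation and 75.0 for salicylic acid genes. Against random lists of the same size only the last of these lay above the upper end of their central 95% range (71.5). Its permutation p was 0.0104, not adjusted over these 8 lists. The 4 shared genes, WRKY33, WRKY40, WRKY46 and WRKY53, are all in the salicylic acid list, each with a percentile above its median. That list was not scored without them, so its value cannot show whether a raised spread extends beyond the touch genes. A sustained salicylic acid response with its late outputs is argued against by PR1 (log2 fold change of -6.92 in the authors' deposited table), PR2 and PR5, which were lower. Those values were known before the question was asked. A salicylic acid response without these outputs stays open, since SARD1, PAD4, EDS1 and EDS5 were higher. Handling at harvest and a response to the mutation that varies between seedlings both stay open, since no value per library was analysed here.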
